A study of Mus musculus with 8 samples.

How the data were processed

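Total brain of 3 wild-type and 5 Cstf2 D50A mice, all aged 50 days, was homogenised, and 3′ end libraries were made from total RNA with the QuantSeq 3′ mRNA-Seq REV kit, per the labels' protocols. This kit primes on the poly(A) tail, so that each read marks the 3′ end of a transcript. The submitters' processing notes name FastQC 0.11.3, STAR 2.5, HTSeq 0.6.0 and the mouse build mm9, without saying what each was used for. How the authors picked the sites, filtered reads primed inside transcripts, or used strand when counting is not given in the sources used here, so genes that overlap, and close paralogs, cannot be separated with certainty. The authors deposited raw read counts per site and library, per the file headers, in 2 tables as whole-number counts: a proximal and a distal site within the 3′-most exon, and a site in an upstream exon beside the 3′-most exon. The values are whole numbers whose totals differ between libraries, and they were used as deposited. All value columns were assigned to a sample through the library code in its title, and 0 were left unused.

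Samples were grouped by the genotype in the labels, which describe separate animals and name no batch or pairing. Replicate numbers follow the order of the sample records and only name the libraries. Libraries of a genotype were compared with a chi-square test of their counts over pairs: chi-square per degree of freedom ran from 3.99 to 114, so none was a second copy of another library of its genotype; libraries of different genotypes were not compared in this way. The 2 tables share reads: in all 4038 genes listed in both, the count for the 3′-most exon was at least the sum of the proximal and distal counts in every library, with a median ratio of 1.048 and equality in 389 genes. Some pairs carry the counts of another pair in all libraries (81 in the first table with 23 distinct sets of counts, and 23 in the second with 5). Of these, 36 and 16 are protocadherin or protocadherin-type genes, which share last exons, and all of them are uncertain. The sites of a pair lie a median of 629 bases apart (quartiles 139 and 1803). Symbols are those of the files; 97.8% and 97.6% matched a current symbol in a RefSeq table of another build (GRCm38.p6), from which no position was taken and only gene lengths were used.

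A pair was tested where both sites together averaged 20 or more reads per library and each site had 10 or more reads in all, which kept 7876 of 7951 and 6001 of 6147 pairs. Site usage was tested with edgeR's quasi-likelihood F test on the counts of both sites, with the library as a block and the interaction of site and genotype as the coefficient, so that the depth of a library cancels; a positive log2 change means relatively more distal (or 3′-most exon) reads in mutants. Abundance was tested on the sum of both sites with TMM scaling and genotype as the only term, and levels are given as log2 CPM (counts scaled to a common library total), so levels are relative to the genes of that table. Standard errors were taken as the log2 change over the square root of F. p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The median over pairs of the log2 ratio, with 0.5 added to each count, was compared between genotypes by an exact two-sided permutation test over 56 assignments. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. DESeq2 left the adjusted p undefined for 5 and 2 genes in the abundance tests, which were kept out of the counts.

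The tests, the filter, the alternatives, 19 gene lists and the rule for named genes were fixed before the data were examined. The lists were the cleavage and polyadenylation machinery, neuronal RNA-binding proteins, glutamatergic postsynapse, GABAergic synapse and interneurons, presynaptic vesicle and release, voltage-gated ion channels, axon guidance and cytoskeleton, X-linked intellectual disability, neurotrophin and MAPK/mTOR signalling, the ubiquitin-proteasome system, oxidative phosphorylation, ribosomal proteins, immediate early genes, and markers of oligodendrocytes, astrocytes, microglia, endothelium and pericytes, choroid plexus with ependyma and blood, and excitatory neurons. Each list of 5 or more measured members was tested with camera from limma at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists of a table. Lists of cerebellar granule cell, Purkinje cell, cortex and hippocampus, and striatum markers were written after the values had been seen, and a second cerebellar list of 18 genes was written before its genes were looked at. Named pairs were to be those past the threshold with a mean of 50 or more reads and no overlap of the genotypes, the 10 with the largest change in share per direction (the 5 with the largest fold for abundance), together with Cstf2, Cstf2t and up to 4 members of each list. As edgeR called no pair, the same rule was applied to the calls of DESeq2, a choice made after the values were seen; other genes named were also chosen then.

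The alternatives fixed at the start were DESeq2, limma on log2 ratios with 0.5 or 5 added, centred ratios, no filter or a mean of 100 reads, a smallest change of 5 percentage points, the mean over pairs in place of the median ratio, reads pooled per genotype with Fisher's exact test, DESeq2 size factors or no scaling for abundance, thinning to the shallowest library, and leaving out each library in turn. Added after seeing the data were the removal of repeated pairs, a cerebellar marker covariate, and 1 or 2 surrogate variables from sva. Each fit was tested on simulated data with known changes of 1, 2 and 3 on the log2 scale in 67, 67 and 66 genes. Simulated counts were drawn independently for each gene, site and library, without variation shared across genes. Their recovery and false calls therefore need not hold for the real libraries. In the simulation of usage within the exon edgeR recovered 16.4%, 76.1% and 95.5% of pairs changed by 1, 2 and 3 on the log2 scale, with 3 false calls among 7876, and for upstream exons 8.96%, 62.7% and 95.5%, with 7 false calls among 6001. For abundance it recovered 70.1%, 97% and 98.5% with 8 false calls in the first table, and 82.1%, 98.5% and 100% with 10 in the second. DESeq2, on whose calls the naming rests, made 13 false usage calls within the exon and 6 for upstream exons, and 21 and 25 false abundance calls, in the same simulations. The median tested pair had 440 reads per library in the first table and 459 in the second. Intervals and floors given for reads cover counting error only, since the reads carry no molecular identifiers.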

Results

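Polyadenylated 3′ ends were sequenced from total brain of 8 mice killed on postnatal day 50. Of these, 3 were wild type and 5 carried Cstf2 D50A, an aspartate-to-alanine exchange at residue 50. It lies in the RNA recognition motif of CSTF2, the cleavage stimulation factor subunit that binds downstream of polyadenylation sites. The series title ties the mutation to intellectual disability and faulty 3′ end formation, so the question was whether the choice of site differs between the genotypes. One deposited table gives reads at a proximal and a distal site within the 3′-most exon of 7951 genes, and the other gives reads at a site in an upstream exon and in the 3′-most exon of 6147 genes. The first table held 9616953, 17530761 and 11858975 reads in wild type 1, 2 and 3, and 10177902, 11984749, 12603351, 13449054 and 11498231 in mutant 1 to 5. The second held 7075383, 13145966 and 8941471 reads in wild type and 7768925, 9082675, 9500640, 10279635 and 8735539 in mutants. Frrs1l took the largest part of the first table in every library, from 3.14% to 6.26%.

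Cstf2 mRNA itself had the same level in both genotypes within the spread of the animals, at 8.52 ± 0.129 log2 CPM in wild type (SD, n = 3) and 8.52 ± 0.146 in mutants (SD, n = 5), with an edgeR log2 change of -9.4e-05 (SE 0.126, adjusted p = 1). A coding substitution need not alter this count, so it does not check the labels. The distal site of Cstf2 held 97.5 ± 0.406% of its reads in wild type and 98.0 ± 0.346% in mutants (log2 change 0.35, SE 0.202, edgeR adjusted p = 0.442). The 3′-most exon held 99.8 ± 0.0625% and 99.7 ± 0.12% against an upstream exon (log2 change -0.64, SE 0.41, edgeR adjusted p = 0.482). Cstf2t, the autosomal paralog, was not analysed here. Among 29 measured members of the cleavage and polyadenylation machinery, none passed edgeR's test in site usage within the exon, with 4 at an unadjusted p under 0.05 toward the distal and 1 toward the proximal site and none called by DESeq2. Pcf11, a termination factor, had a log2 change in usage of -2.15 (SE 0.716, edgeR adjusted p = 0.388). For Wdr33, which binds the polyadenylation signal, it was 1.16 (SE 0.403, edgeR adjusted p = 0.388).

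Within the 3′-most exon, distal sites held more of the reads in mutants at Hnmt, which encodes the histamine methyltransferase, with 69.95 ± 16.6% in wild type and 97.0 ± 0.948% in mutants, and at Max, the partner of MYC, with 27.5 ± 7.41% and 48.2 ± 7.05% (SD, n = 3 and 5). Zyg11b, a ubiquitin ligase adaptor, stood at 11.2 ± 3.21% and 24.3 ± 2.97%, and Ugt8a, which makes the galactolipids of myelin, at 1.40 ± 0.617% and 6.19 ± 1.69%. The opposite was measured at Abt1, with 70.7 ± 9.2% and 29.0 ± 17.9%, at Cnpy4, with 57.1 ± 9.17% and 27.8 ± 9.42%, and at Kmt5a, the histone H4 lysine methyltransferase, with 73.3 ± 4.64% and 54.2 ± 3.13%. DESeq2 called these pairs, with log2 changes of 3.64 (SE 0.651, adjusted p = 0.000185) for Hnmt, 1.32 (SE 0.335, adjusted p = 0.0369) for Max, 1.38 (SE 0.289, adjusted p = 0.00352) for Zyg11b, 2.21 (SE 0.425, adjusted p = 0.000827) for Ugt8a and -1.19 (SE 0.294, adjusted p = 0.0369) for Kmt5a. edgeR, the main test, called none of them (adjusted p from 0.355 to 0.388). Over the alternatives the adjusted p of each reached 0.824, the highest value, and for Hnmt it was lowest with DESeq2. In all 5 mutants the share lay beyond all 3 wild-type values, which the naming rule required, so it adds no support. The sites of Hnmt lie 391 bases apart, at positions 23858822 and 23858431 on the mm9 build as the files give them, and those of Ugt8a 4701 bases apart, at 125568428 and 125563727; the files give no chromosome.

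Further pairs that DESeq2 placed toward the distal site without overlap of the genotypes were Ccnyl1, Mfsd14a, Dusp7, Rbm24 and Prr18. The distal share of Dusp7, a MAP kinase phosphatase, was 88.25 ± 7.13% in wild type and 98.6 ± 0.94% in mutants, and that of Rbm24, an RNA-binding protein, 87.7 ± 3.77% and 97.5 ± 2.37% (SD, n = 3 and 5). The sites of Mfsd14a lie only 29 bases apart. Mutant 5 lay nearest to wild type in several of them, with 19.1% for Zyg11b where the other mutants had 24.6% to 26.25%, and 68.3% for Mfsd14a where they had 87.7% to 94.85%. Wild type 3 lay nearest to the mutants, with 87.4% for Hnmt and 35.95% for Max. DESeq2's 21 calls also held pairs in which the genotypes overlapped, among them Dnm1, the dynamin of synaptic vesicle endocytosis, with a distal share of 97.8% in wild type and 92.3% in mutants, and Pde4b, a cAMP phosphodiesterase, with 11.1% and 40.5%.

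**Figure D1:**
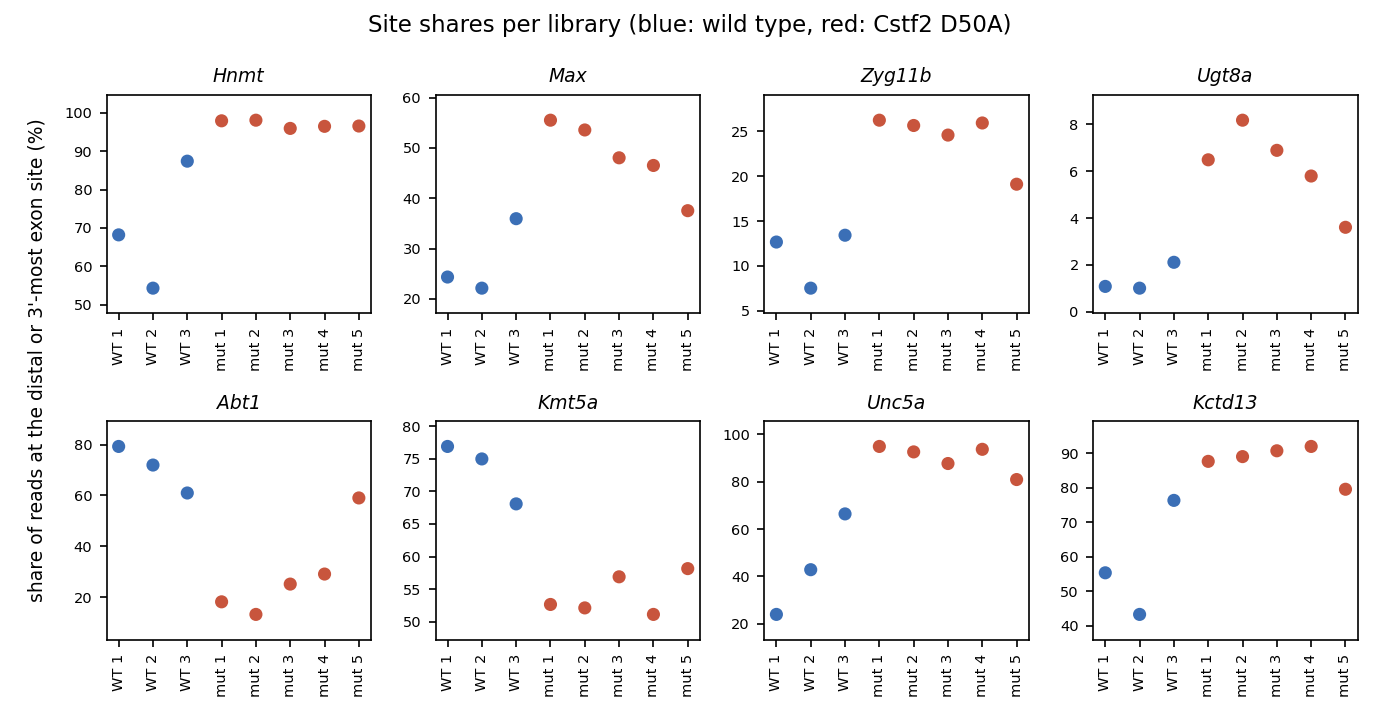
Share of reads at the distal site of the 3′-most exon (Hnmt, Max, Zyg11b, Ugt8a, Abt1, Kmt5a) or at the 3′-most exon against an upstream exon (Unc5a, Kctd13), in percent, 1 point per library and a separate vertical scale per gene. The genotypes do not overlap in any panel, which was a condition for naming these genes. For Max wild type 3 (35.95%) and mutant 5 (37.5%) are the closest libraries.

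Over all 7876 tested pairs edgeR called 0, with 1003 at an unadjusted p under 0.05 where chance gives 394. Of the 1003, 675 pointed to the distal and 328 to the proximal site. DESeq2 called 15 toward the distal and 6 toward the proximal site, and limma called 0. The genotypes did not overlap in 327 pairs (4.15%), against 3.57% by chance. The median log2 ratio of distal to proximal reads averaged 0.12 ± 0.0802 in wild type (SD, n = 3) and 0.27 ± 0.104 in mutants (SD, n = 5), a difference of 0.145 with an exact two-sided permutation p of 0.107, where 56 assignments allow no p below 0.0179. Without wild type 3, edgeR called 1 pair, Hnmt, toward the distal site (log2 change 4.34, adjusted p = 0.0231, against 0.000185 to 0.824 over its alternatives).

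**Figure D2:**
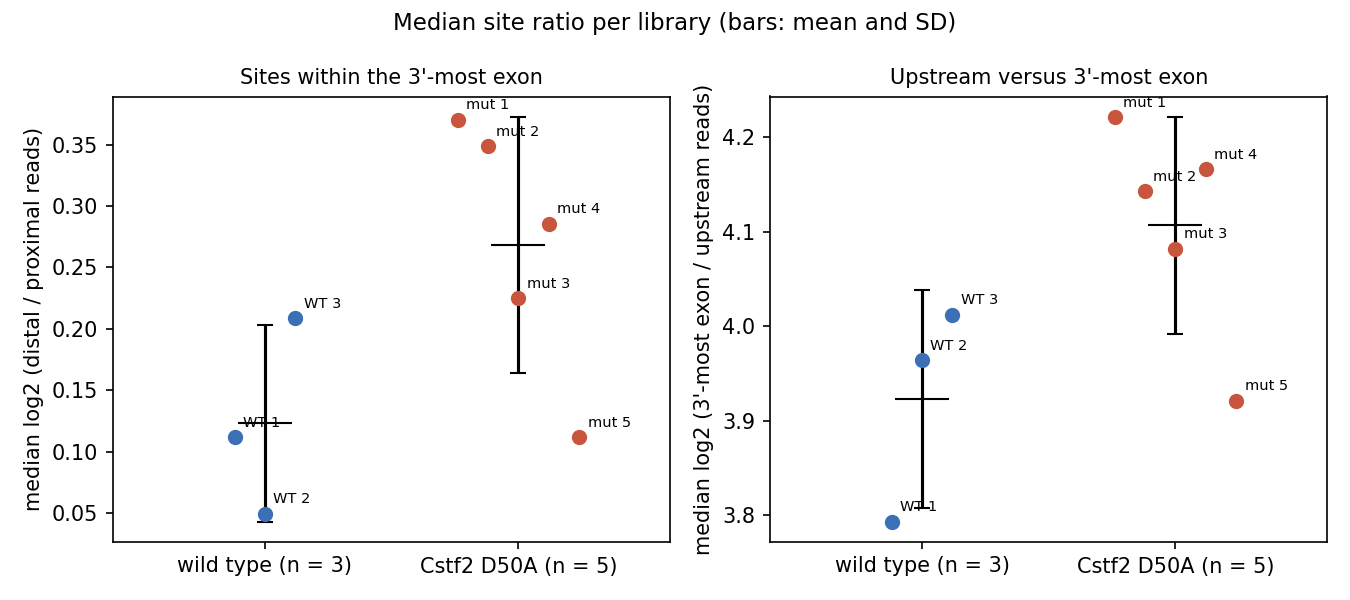
Median over tested pairs of the log2 ratio of distal to proximal reads (left) and of reads in the 3′-most exon to an upstream exon (right), 1 point per library, with the mean and SD of each genotype as bars. Mutant 5, at 0.11 and 3.92, lies within the range of the wild-type libraries in both panels.

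No fixed gene list stood apart from other genes in usage within the exon: adjusted p from camera ran from 0.625 for the ubiquitin-proteasome system to 0.996. Median log2 changes in usage were 0.277 for that list, 0.214 for the cleavage and polyadenylation machinery, 0.111 for neuronal RNA-binding proteins, 0.219 for the glutamatergic postsynapse, 0.115 for the GABAergic synapse, 0.125 for presynaptic release, 0.147 for voltage-gated channels, 0.0627 for axon guidance, 0.219 for X-linked intellectual disability genes and 0.149 for neurotrophin and MAPK/mTOR signalling. They were 0.0776 for oxidative phosphorylation, 0.186 for ribosomal proteins, 0.257 for immediate early genes, 0.162 for oligodendrocyte, 0.183 for astrocyte, 0.0697 for microglia, 0.141 for endothelial, 0.479 for choroid plexus and 0.155 for excitatory neuron markers. For all pairs the median was 0.115, and 59.2% of pairs lay above 0. Over all pairs edgeR called 0 members of any list; adjusted over the list alone, Ugt8a passed among the oligodendrocyte markers (adjusted p = 0.00226). For axon guidance, neuronal RNA-binding proteins, presynaptic release and microglia markers the medians lay above 0 while camera, which compares a list with all other pairs, pointed toward the proximal site.

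Between an upstream and the 3′-most exon, more reads ended in the 3′-most exon in mutants at Unc5a, a netrin receptor in axon guidance, with 44.4 ± 21.2% in wild type and 89.9 ± 5.74% in mutants (SD, n = 3 and 5). The same held for Mtif2, the mitochondrial translation initiation factor, with 17.6 ± 12.5% and 49.9 ± 10.6%, and for Kctd13, an adaptor of a cullin ubiquitin ligase, with 58.3 ± 16.7% and 87.8 ± 4.89%. DESeq2 called all 3, with log2 changes of 3.56 for Unc5a (SE 0.655, adjusted p = 0.000333), 2.42 for Mtif2 (SE 0.582, adjusted p = 0.0428) and 2.36 for Kctd13 (SE 0.546, adjusted p = 0.0302), and edgeR called none (adjusted p of 0.214, 0.287 and 0.287). All 5 mutants lay above all 3 wild types, again as the naming rule required. Over the alternatives the adjusted p ran from 0.000333 to 0.674 for Unc5a, from 0.0208 to 0.674 for Mtif2 and from 0.0155 to 0.674 for Kctd13. Without mutant 5 edgeR called all 3 (adjusted p of 0.00554, 0.0208 and 0.0155), as it did without wild type 3 (0.0209 for each). Without mutant 5 the mean of cerebellar markers was 4.99 to 5.11 log2 CPM in mutants and 6.40 to 6.70 in wild types. That fit therefore cannot separate genotype from cerebellar content. DESeq2's other calls were Fbxl16, with 91.7% and 98.8%, and, toward the upstream exon, Frmd8, with 97.6% and 84.8%. Wild type 3 was the nearest to the mutants for Unc5a (66.4%) and mutant 5 the nearest to wild type (80.9%).

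Small shifts were measured in synaptic genes whose reads nearly all end in the 3′-most exon. Its share was 99.5 ± 0.146% in wild type and 99.8 ± 0.0485% in mutants for Syp, the synaptophysin of synaptic vesicles, 97.7 ± 1.28% and 99.1 ± 0.116% for the GABA-B receptor subunit Gabbr2, 98.3 ± 0.964% and 99.6 ± 0.342% for the GABA-synthesising enzyme Gad1, and 99.75 ± 0.194% and 98.7 ± 0.844% for the GABA-A receptor subunit Gabra4 (SD, n = 3 and 5). Adjusted over the list alone, edgeR's p was 0.0235 for each of Gabbr2, Gad1 and Gabra4 among 18 GABAergic synapse genes, 0.0469 for Syp among 42 presynaptic and 0.0324 among 29 X-linked intellectual disability genes, 0.00196 for Unc5a among 55 axon guidance genes, and 0.0356 for the ubiquitin-conjugating enzyme Ube2d3 among 47 proteasome genes. Over all pairs none of these passed edgeR's test, at adjusted p from 0.214 to 0.287. Gabra4 and Ube2d3 moved toward the upstream exon, the others toward the 3′-most exon.

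Over all 6001 tested pairs edgeR called 0, with 834 at an unadjusted p under 0.05 (618 toward the 3′-most exon, 216 toward the upstream exon) where chance gives 300. DESeq2 called 4 and 1, and limma 0. The genotypes did not overlap in 353 pairs (5.88%), against 3.57% by chance. The median log2 ratio of 3′-most exon to upstream reads averaged 3.92 ± 0.115 in wild type (SD, n = 3) and 4.11 ± 0.115 in mutants (SD, n = 5), a difference of 0.184 with an exact two-sided permutation p of 0.0893. Single libraries decided these counts: without mutant 5 edgeR called 178 pairs toward the 3′-most and 65 toward the upstream exon, and the difference of medians was 0.23 (exact permutation p = 0.0286), while without wild type 3 it called 106 and 39. The fit without mutant 5 cannot separate genotype from cerebellar content. Leaving out wild type 1 lowered the difference of medians to 0.119 (exact permutation p = 0.238).

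No list stood apart in this usage either, at adjusted p from camera between 0.532 and 0.91 over 16 lists. Median log2 changes were 0.361 for the glutamatergic postsynapse, 0.332 for voltage-gated channels, 0.318 for X-linked intellectual disability genes, 0.306 for presynaptic release, 0.304 for the GABAergic synapse, 0.287 for axon guidance, 0.156 for neuronal RNA-binding proteins, 0.133 for neurotrophin and MAPK/mTOR signalling, 0.102 for the cleavage and polyadenylation machinery and 0.0608 for the ubiquitin-proteasome system, beside 0.169 over all pairs. They were -0.0646 for oxidative phosphorylation, 0.0468 for ribosomal proteins, 0.265 for oligodendrocyte, 0.299 for astrocyte, 0.636 for endothelial and 0.109 for excitatory neuron markers. Immediate early genes (0.587), microglia (0.0579) and choroid plexus markers (-0.207) had fewer than 5 members and were not tested. For neuronal RNA-binding proteins, the ubiquitin-proteasome system and ribosomal proteins the median lay above 0 and camera's direction was toward the upstream exon.

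Shifts of the same gene were compared between the 2 tables. Of 4007 genes tested in both, edgeR called 0 in each, and DESeq2 called 7 toward the distal site and 3 toward the 3′-most exon with 0 shared, and 3 and 1 in the opposite direction with 0 shared. So few calls cannot test an overlap. Spearman's correlation of the log2 changes was 0.0605 across these genes, which are not independent replicates. The tables share reads, since the 3′-most exon count was at least the sum of its proximal and distal sites in all 4038 genes listed in both.

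For the summed reads of both sites, mutants had higher levels of Rgs14, a regulator of G protein signalling, at 3.60 ± 0.622 log2 CPM in wild type and 4.95 ± 0.437 in mutants (SD, n = 3 and 5), and of Nprl3, a subunit of the GATOR complex upstream of mTORC1, at 1.71 ± 0.732 and 3.12 ± 0.347. Ddx19b, an RNA helicase of mRNA export, stood at 2.82 ± 0.493 and 4.03 ± 0.384, Bod1l at 1.31 ± 0.493 and 2.59 ± 0.472, and Xxylt1, a xylosyltransferase, at 2.36 ± 0.759 and 3.67 ± 0.318. Fam107a was lower, at 7.24 ± 0.234 and 6.66 ± 0.128. DESeq2 called these 6, with log2 changes from 1.20 for Ddx19b (SE 0.291, adjusted p = 0.0322) to 1.35 for Nprl3 (SE 0.335, adjusted p = 0.0328), and -0.60 for Fam107a (SE 0.157, adjusted p = 0.0479). All 5 mutants lay beyond all 3 wild types in each, as the naming rule required. Over the alternatives the adjusted p of each reached 0.743. edgeR called 0 of 7876, at a smallest adjusted p of 0.345, with 1133 at an unadjusted p under 0.05 (576 higher, 557 lower) where chance gives 394, and DESeq2 called 25 higher and 1 lower. The genotypes did not overlap in 375 genes (4.76%), against 3.57% by chance. Without mutant 5 edgeR called 18 higher and 52 lower, among them Bod1l (adjusted p = 0.0348), Rgs14 (0.0355) and Ddx19b (0.0452). In that fit genotype again goes with cerebellar content. Mutant 5 lay nearest to wild type in Rgs14 (4.19), Nprl3 (2.52) and Xxylt1 (3.10).

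Ribosomal protein genes were lower as a group in the mutants (camera adjusted p = 5.45e-09; adjusted p = 0.492 with an estimated correlation), with a median log2 change of -0.531 and 29 of 42 measured members below 0 at an unadjusted p under 0.05. Rpl38 stood at 9.74 ± 0.397 log2 CPM in wild type and 9.25 ± 0.0678 in mutants, and Rps3 at 11.1 ± 0.645 and 10.45 ± 0.231 (SD, n = 3 and 5), while Rpl28 was higher, at 5.49 ± 0.92 and 7.13 ± 0.852 (DESeq2 adjusted p = 0.0499, edgeR adjusted p = 0.345). Wild type 1 stood apart in this list: the median deviation from the wild-type mean was 0.625 there, -0.174 in wild type 2 and -0.464 in wild type 3, beside -0.353 to -0.56 in the mutants. Without it the list's median change between genotype means of log2 CPM, a measure apart from edgeR's log2 change, went from -0.453 to -0.164. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain where reads were split. Oxidative phosphorylation genes were lower too (camera adjusted p = 1.71e-07, and 0.492 with an estimated correlation of 0.298). Their median log2 change was -0.322, with 24 of 49 members below 0 at an unadjusted p under 0.05. Wild type 1 at 0.303 was again above wild type 2 (-0.0478) and wild type 3 (-0.256). The mutants ran from -0.462 to -0.194, so wild type 3 lay within their range. Without wild type 1 the median change of this list between genotype means of log2 CPM went from -0.309 to -0.18. Ndufs4, of respiratory complex I, stood at 7.60 ± 0.484 and 7.03 ± 0.144.

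Glutamatergic postsynapse genes were higher in mutants as a group (median 0.269, camera adjusted p = 7.98e-05; adjusted p = 0.492 with an estimated correlation), with 13 of 44 members at an unadjusted p under 0.05, among them the metabotropic receptor Grm8, at 3.13 ± 0.336 and 4.01 ± 0.278 log2 CPM (SD, n = 3 and 5). Per library the median deviation of this list was -0.258, -0.0167 and 0.199 in wild type 1 to 3 and 0.417, 0.294, 0.281, 0.292 and 0.215 in mutant 1 to 5. That of 19 cortex and hippocampus markers ran beside it, at -0.387, 0.21 and 0.155 in wild type and 0.402, 0.443, 0.307, 0.292 and 0.253 in mutants, so the tissue content of the libraries was not separated from this change. These markers were listed after the values were seen, and 15 of the 23 listed are in fixed lists. Part of the likeness may come from shared genes. Axon guidance genes (median 0.235, 10 of 74, camera adjusted p = 0.000108), voltage-gated channels (0.23, 7 of 44, camera adjusted p = 0.000855) and endothelial markers (0.392, 2 of 11, camera adjusted p = 0.0443) were higher, all at adjusted p = 0.492 with an estimated correlation. Examples were the collapsin response mediator Dpysl3, at 4.68 ± 0.346 and 5.47 ± 0.323, the sodium channel subunit Scn4b, at 4.44 ± 0.692 and 5.94 ± 0.589, and the glucose transporter Slc2a1, at 4.33 ± 0.926 and 5.49 ± 0.57. Among wild types, wild type 1 lay lowest in the channels (-0.228, 0.0406 and 0.256), and mutant 5 lowest among mutants in the endothelial list (0.0466, the others 0.351 to 0.427). Without wild type 1 the median changes between genotype means of log2 CPM were smaller. They went from 0.287 to 0.156 for the glutamatergic list, from 0.235 to 0.147 for axon guidance, from 0.258 to 0.138 for channels and from 0.452 to 0.268 for endothelial markers. Without wild type 3 this median change of the channels was 0.388. Presynaptic genes did not pass (median 0.104, camera adjusted p = 0.14). Their median change between genotype means of log2 CPM, 0.112, became -0.0246 without wild type 1 and 0.199 without wild type 2.

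The remaining lists did not stand apart by camera. Their median log2 changes were 0.106 for the cleavage and polyadenylation machinery (adjusted p = 0.192), 0.00226 for neuronal RNA-binding proteins (0.768), 0.161 for the GABAergic synapse (0.271), 0.135 for X-linked intellectual disability genes (0.151), 0.075 for neurotrophin and MAPK/mTOR signalling (0.168), -0.027 for the ubiquitin-proteasome system (0.63) and 0.118 for immediate early genes (0.225). They were -0.185 for oligodendrocyte (0.192), -0.0747 for astrocyte (0.63), -0.044 for microglia (0.63), -0.185 for choroid plexus (0.63) and 0.166 for excitatory neuron markers (0.155). Adjusted over the list alone, the oligodendrocyte precursor genes Pdgfra and Gpr17 were higher in mutants by edgeR, at adjusted p of 0.0429 and 0.0491. Pdgfra stood at 3.24 ± 0.633 and 4.78 ± 0.558 log2 CPM and Gpr17 at 4.16 ± 0.578 and 5.19 ± 0.299 (SD, n = 3 and 5), against a median below 0 for the list. Over all genes edgeR's adjusted p was 0.345 for both.

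In the table of upstream exons, oxidative phosphorylation (median -0.305, 16 of 35 below 0 at an unadjusted p under 0.05) and ribosomal proteins (-0.522, 13 of 21) were lower, both at a camera adjusted p of 2.46e-06. Higher were the glutamatergic postsynapse (0.197, adjusted p = 0.000338), axon guidance (0.217, 0.000468), presynaptic release (0.223, 0.00413) and voltage-gated channels (0.176, 0.00451). Cortex and hippocampus markers ran beside the higher lists, at median deviations of -0.391, 0.243 and 0.182 in wild type 1 to 3 and 0.339, 0.333, 0.371, 0.26 and 0.227 in mutant 1 to 5, where presynaptic release had -0.292, 0.13 and 0.133 and 0.294, 0.202, 0.222, 0.228 and 0.222. Tissue content was not separated from these changes in either table. The cortex and hippocampus list was written after the values were seen and shares genes with the fixed lists. All 6 fixed lists were at adjusted p = 0.427 with an estimated correlation, and wild type 1 was again apart in ribosomal proteins (0.603, wild type 2 -0.169, wild type 3 -0.449). Cacna2d3, a calcium channel subunit, passed edgeR's test adjusted over the list alone (log2 change 0.61, SE 0.138, adjusted p = 0.0451; 0.327 over all genes). The other lists did not pass. Their medians were -0.00862 for the cleavage and polyadenylation machinery, 0.0192 for neuronal RNA-binding proteins, 0.0894 for the GABAergic synapse, 0.16 for X-linked intellectual disability genes, 0.0823 for neurotrophin and MAPK/mTOR signalling, -0.00126 for the ubiquitin-proteasome system, -0.228 for oligodendrocyte, -0.0792 for astrocyte, 0.08 for endothelial and 0.163 for excitatory neuron markers. Sets of immediate early genes (0.132), microglia (0.115) and choroid plexus markers (0.0837) were too few to test. For the cleavage and polyadenylation machinery the median lay below 0 and camera's direction was upward. Without wild type 1 the median changes between genotype means of log2 CPM became smaller. They went from -0.453 to -0.14 for ribosomal proteins, from -0.29 to -0.187 for oxidative phosphorylation, from 0.257 to 0.113 for the glutamatergic postsynapse and from 0.223 to 0.141 for axon guidance. That of presynaptic release went from 0.248 to 0.0648, which no longer passed camera at an unadjusted threshold of 0.05, and without wild type 3 that of ribosomal proteins was -0.68. edgeR called 0 of 6001 genes, with 903 at an unadjusted p under 0.05 (456 higher, 447 lower) where chance gives 300, and DESeq2 called 0. The genotypes did not overlap in 287 genes (4.78%), against 3.57% by chance. Without mutant 5, where genotype goes with cerebellar content, edgeR called 25 higher and 46 lower.

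Transcripts of the cerebellum set single libraries apart within the mutant group. Cbln3, a cerebellin of granule cells, had 8.45, 8.26 and 8.18 log2 CPM in wild type 1 to 3, and 0.58, 1.12, 0.74, 0.20 and 8.09 in mutant 1 to 5. Gabra6, the GABA-A receptor subunit of granule cells, had 280, 400 and 300 reads in wild type and 2, 2, 0, 0 and 253 in mutants; 0 reads allow up to 3 at 95% confidence by counting error alone. Car8, a Purkinje cell gene, had 7.05, 6.53 and 6.58 in wild type and 2.57, 2.63, 2.76, 2.80 and 6.43 in mutants, and Zic1, a granule cell transcription factor, 9.54, 9.03 and 8.87 against 6.93, 6.95, 7.17, 7.23 and 8.97. With all libraries edgeR called none of the 4, at log2 changes of -2.50 for Cbln3 (SE 1.6, adjusted p = 0.407), -2.57 for Gabra6 (SE 1.27, 0.345), -2.26 for Car8 (SE 0.889, 0.345) and -1.47 for Zic1 (SE 0.461, 0.345). Without mutant 5 edgeR called all 4, at -7.67 for Cbln3 (adjusted p = 7.68e-08), -8.20 for Gabra6 (2.61e-06), -4.06 for Car8 (1.63e-06) and -2.10 for Zic1 (0.000352). Over the alternatives these were the lowest values, and the highest were 0.743 for Cbln3, Car8 and Zic1 and 0.727 for Gabra6. Over 11 measured granule cell markers, the median deviation from the wild-type mean was 0.225, -0.0574 and -0.198 in wild type 1 to 3, and -0.963, -1.20, -1.26, -1.09 and -0.126 in mutant 1 to 5. Over 9 Purkinje cell markers it was 0.0173, -0.208 and 0.177 in wild type and -0.28, -0.365, -0.474, -0.642 and -0.0622 in mutants. These marker lists were written after the values had been seen. The first component of site ratios within the exon, with 60.1% of the variance, was -0.452, -0.501 and 0.0934 in wild type 1 to 3 and 0.444, 0.354, 0.0659, 0.322 and -0.326 in mutant 1 to 5.

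**Figure D3:**
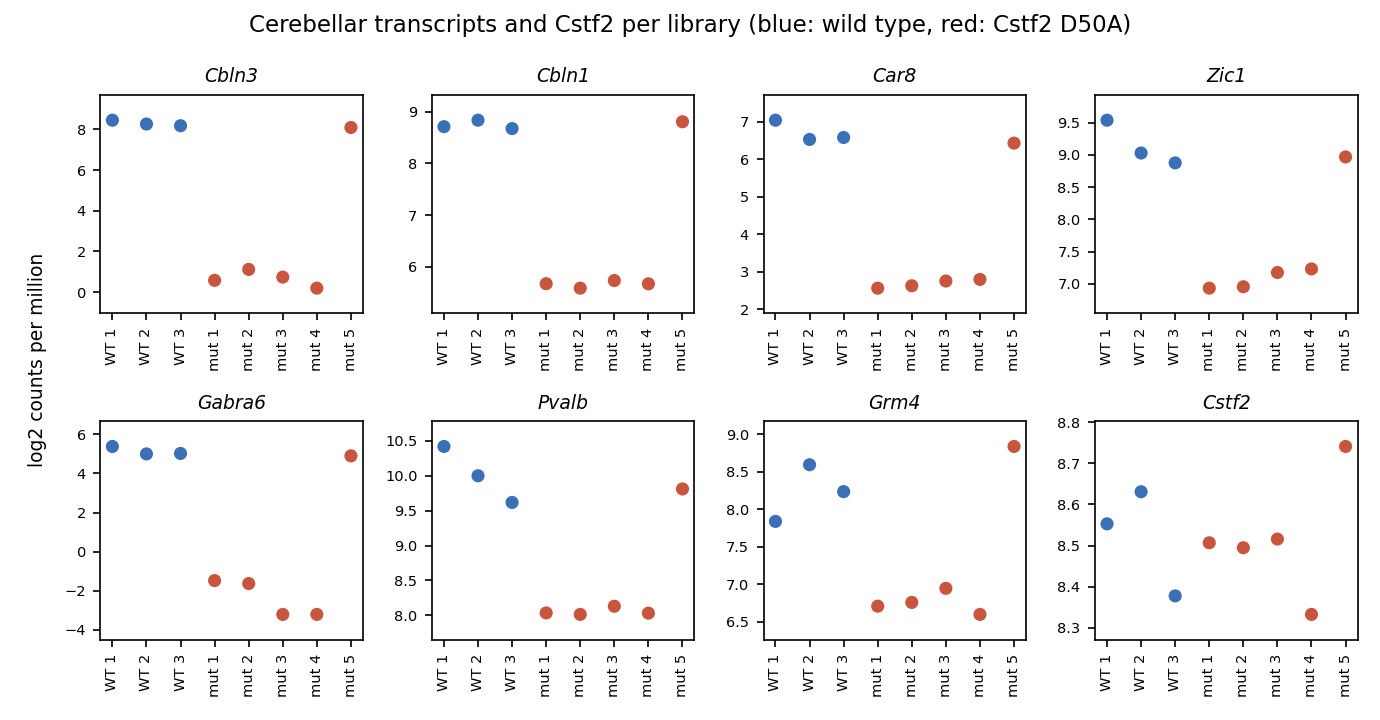
Abundance in log2 CPM of 7 genes of the cerebellum and of Cstf2, 1 point per library and a separate vertical scale per gene; Gabra6, Pvalb and Grm4 are from the table of upstream exons. Mutant 5 lies near the wild-type libraries in the 7 cerebellar genes (8.09 for Cbln3), the other mutants far below (0.20 to 1.12), and Cstf2 spans 8.33 to 8.74 over all libraries.

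**Figure D4:**
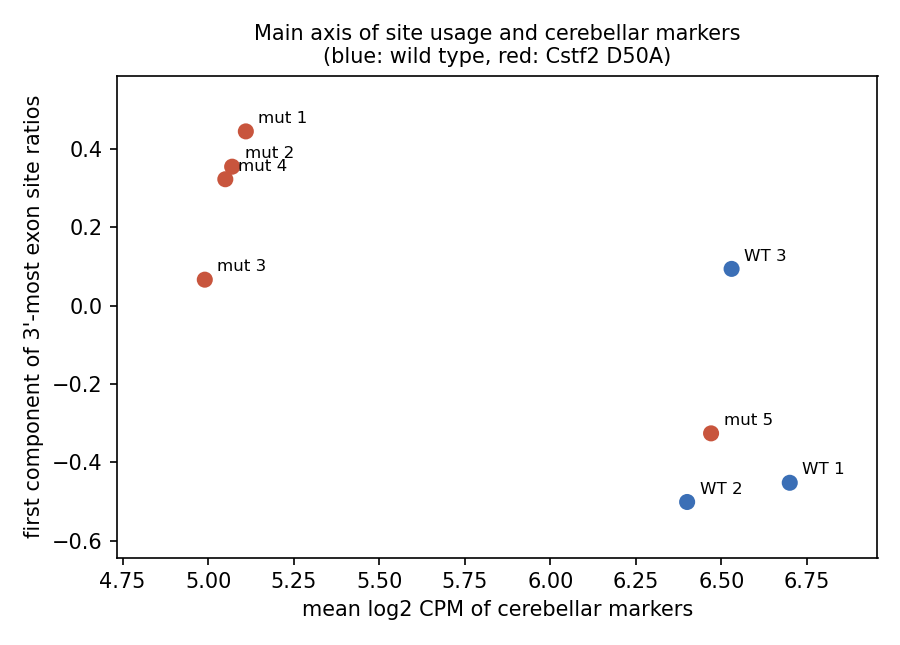
First principal component of site ratios within the 3′-most exon (vertical, unitless) against the mean log2 CPM of 20 cerebellar markers (horizontal), 1 point per library. Mutant 5 (-0.326) lies with wild type 1 and 2 on both axes, and wild type 3 (0.0934) has a high marker mean of 6.53.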

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

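Leaving out each library was planned, and the second cerebellar list and the thinning to equal depth were set before their results; the tests of the granule cell list in mutant 5, of the positions of left-out libraries, of spans and gene length on the main axis and of exchanged labels were chosen after the result was seen. Of 124 values examined, 22 were marked because 1 library lay far from the others of its genotype; chance marks about 1 in 20 groups, which gives 6. The 22 cannot be set against the 6, because the cerebellar genes, Pomc and the region lists were chosen after their values were seen. Among 70 values of lists fixed before that, 2 were marked, where chance gives 4.

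Cerebellar transcripts were high in mutant 5 and low in the other mutants: Cbln3 stood at 8.09 (nearest other mutant 1.12), Cbln1 at 8.81 (5.73), Car8 at 6.43 (2.80), Neurod1 at 7.73 (5.22) and Zic1 at 8.97 (7.23) log2 CPM. In the table of upstream exons Gabra6 stood at 4.90 (-1.49), Pvalb at 9.81 (8.13) and Grm4 at 8.84 (6.94), and the granule cell list at -0.126 (-0.963) and -0.0563 (-0.795) in the first and second table. On a second list, median deviations were 0.102, -0.005 and 0.13 in wild type 1 to 3 and -0.92, -0.773, -0.822, -0.756 and 0.0632 in mutant 1 to 5, and 4 of 7 measured genes had mutant 1 to 4 lowest, against 8.05% of tested genes (Fisher's exact p = 0.0012; genes are not independent replicates). This is consistent with less cerebellar tissue in mutant 1 to 4, possibly from dissection. A loss of cerebellar transcripts caused by the mutation in every animal cannot be told apart. Mutant 5 shows none in the granule cell list (-0.126), but its label rests on the records alone. Exchanging its label with that of wild type 3 would not restore such a loss, since wild type 3 (-0.198) shows none either. Only a mutant 5 that is wild type, with no wild-type library being a mutant, would leave room for it.

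Calls of upstream exon usage appeared when mutant 5 was left out, 243 against 0. In those pairs, chosen without it, mutant 5 lay at 0.164 on a scale from wild type (0) to the other mutants (1). Mutants 1 to 4, left out in turn, lay at 1.20, 1.10, 0.732 and 1.01 in as many pairs of smallest p. Of those pairs 0 were called, and their scale included mutant 5. The low position goes with a mutant 5 library that stands apart. It partly restates that the calls appear only without mutant 5. Wild type 3, with cerebellar transcripts at wild-type level, lay at 0.836 when left out (wild type 1 and 2 at 0.277 and 0.303). This too partly restates that calls appear without that library, 145 against 0. It also rests on 1 library whose label the counts do not check. Cerebellar tissue as the whole cause therefore cannot be told apart. An effect of genotype that mutant 5 lacks was not tested.

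The main axis of site usage within the exon, with 60.1% of the variance, followed genotype only in part. Wild type 3 (0.0934) lay among the mutants, and mutant 5 (-0.326) near wild type 1 (-0.452) and 2 (-0.501). The difference of the genotypes on this axis was not tested. Depth acting through counting noise was excluded, since the axis before and after thinning to equal totals correlated at 1. Thinning does not remove differences in library making that go with depth. Genomic length of the gene, introns included, had a Spearman correlation of 0.0176 with the loadings across pairs, which are not independent replicates. This excludes only a monotonic relation of this usage axis with genomic length. Lengths of transcripts and of 3′-most exons were not tested. For the first component of abundance the correlation with genomic length was 0.261, which leaves gene length open there. Libraries of nearly the same cerebellar marker mean spanned 40% and 62.9% of its range, which argues against cerebellar tissue as the whole cause, but it cannot be told apart, since without 1 library the spans were as small as 12.9% (without mutant 3) and 18.5% (without wild type 3). Exchanged labels of wild type 3 and mutant 5 cannot be told apart from an unnamed factor: with them exchanged edgeR called 2402 pairs, but the counts of Cstf2 do not show the mutation. A split that is no such exchange, mutant 1, 2 and 4 against the rest, also gave 760. Of biological explanations, only cerebellar tissue was tested for this axis.

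The other marked values are these. Mutant 5 stood at 68.3% for Mfsd14a (nearest mutant 87.7%), 19.1% for Zyg11b (24.6%) and 93.4% for Rbm24 (97.6%) in distal share. It stood at 2.52 for Nprl3 (3.18), 4.19 for Rgs14 (5.05) and 3.10 for Xxylt1 (3.74) in log2 CPM. Its endothelial list stood at 0.0466 in abundance (0.351), and its granule cell list at 0.0936 in usage within the exon (-0.402). Mutant 2 had 2839 reads of Pomc, the pituitary and hypothalamic hormone precursor, at 7.84 log2 CPM (3.24). In the table of upstream exons the presynaptic list stood at 0.294 in abundance in mutant 1 (0.228), the Purkinje cell list at 0.821 in usage in mutant 2 (0.0771), and the cortex and hippocampus list at -0.151 in usage in mutant 3 (0.122).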

How the results depend on the processing

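Of the comparisons of main results with alternatives, 155 were the same, 24 counts moved and 1 became stronger. Every main count was 0, so a count was the same only where the alternative also gave 0. Most of the 155 are such counts. Median ratios, single genes and lists were the same where direction and side of 0.05 were kept. Among single genes and lists 438 were the same, 43 became stronger, 13 weaker and 12 reversed. No single gene had passed in the main fit. edgeR's 0 became 15 distal and 6 proximal pairs with DESeq2, 4 toward the 3′-most and 1 toward the upstream exon, and 25 higher and 1 lower in abundance in the first table. Pooling reads, which ignores the animals, gave 2307, 1208, 1389 and 485. With 2 surrogate variables there were 30 higher and 5 lower genes in the first table, 5 and 1 in the second, and 1 pair toward the 3′-most exon. Neither 1 surrogate variable nor the cerebellar marker covariate gave any call. Leaving out libraries gave 0 to 1 distal pairs, 0 to 178 toward the 3′-most and 0 to 65 toward the upstream exon, 0 to 18 higher and 0 to 52 lower genes in the first table and 0 to 25 and 0 to 46 in the second, and a median difference of 0.119 to 0.23 for upstream exons. Cstf2 abundance, near 0, changed sign: 0.0682 and 0.0436 without TMM, and -0.0681 to 0.0442 and -0.0801 to 0.0509 with a library left out. The presynaptic list ran from -0.0246 without wild type 1 to 0.199 without wild type 2. The cause was not tested, except for upstream exon calls without mutant 5, where that library's position was tested above. With a library left out, the median difference within the exon ran from 0.108 without wild type 2 (exact permutation p = 0.286) to 0.188 without wild type 3 (exact permutation p = 0.143). The lowest exact permutation p was 0.0571, without mutant 5. Under the other alternatives the median ratio differed by 0.136 to 0.147 within the exon and 0.162 to 0.199 for upstream exons. No paired analysis was possible because the labels give no pairing. A log2 usage change of 1 was recovered in only 16.4% and 8.96% of simulated pairs. Those pairs were drawn independently and lack the variation shared across genes in the real libraries. Within the exon 95.5% of simulated changes of 3 were recovered, yet Hnmt at 3.56 was not called (edgeR adjusted p = 0.355). These rates therefore need not hold for the real data.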

Other observations

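Lists of brain regions were written after the cerebellar values were seen, and every test in this part was chosen after a result was seen except the split counts at an unadjusted p. Cortex and hippocampus markers, of which 15 of 23 are in other lists, had a median log2 change in abundance of 0.381, with deviations of -0.387, 0.21 and 0.155 in wild type 1 to 3 and 0.402, 0.443, 0.307, 0.292 and 0.253 in mutant 1 to 5. Striatum markers, of which 2 of 16 are in other lists, had 0.212, with 0.0309, -0.0255 and -0.0361 in wild type and 0.394, 0.415, 0.168, 0.102 and -0.0735 in mutants; the sodium channel subunit Scn4b had an edgeR adjusted p of 0.0442 adjusted over the list alone. Granule cell markers (5 of 18 in other lists) had -0.844 and Purkinje cell markers (3 of 18) -0.404. In the table of upstream exons the medians were 0.338, 0.0526, -0.664 and -0.305 in the same order. In usage within the exon they were 0.0863, 0.39, -0.327 and 0.091, and for upstream exons 0.0654, -0.233, 0.429 and -0.012. Of the second cerebellar list, 1 of 18 genes is in another list.

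Each fit was repeated over the 56 ways to split the libraries into 3 and 5. The real genotypes gave 0 edgeR calls in all 4 fits, which all 56 splits must reach, so these counts test nothing about chance. The highest other counts were 2402 and 1079 usage pairs and 3194 and 2312 genes in abundance, all with wild type 1, wild type 2 and mutant 5 against the rest. That split is the labels with wild type 3 and mutant 5 exchanged. Mutant 1, 2 and 4 against the rest, which is no such exchange, came second with 760 and 425 usage pairs and 940 and 891 genes. Both point to a structure of the samples that is not genotype as the labels give it. With the 2 labels exchanged, wild type 3 (cerebellar marker mean 6.53 log2 CPM) would still differ from mutant 1 to 4 (4.99 to 5.11). At an unadjusted p under 0.05, 8 splits reached the 1003 pairs within the exon (highest 3269) and 4 the 834 pairs of upstream exons (highest 1870). In abundance 6 reached the 1133 genes (highest 3954) and 6 the 903 genes (highest 2930). Chance cannot be excluded for these 4 counts at an unadjusted p.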
